A study of Mus musculus with 7 samples.

How the data were processed

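Chromatin immunoprecipitation followed by sequencing (ChIP-seq) was used to map where 2 transcription factors and 3 histone marks sit in the genome of neural progenitor cells. The cells were primary cultures from the forebrain of 12-week-old FVB/N mice at passages 4 to 9. Of the 7 samples, 5 have a peak list: FOXO3, ASCL1, H3K4me1, H3K4me3 and H3K27me3. The 2 no-antibody background samples, 1 in each medium, were not analysed here, so no background level is given beside the peaks. Sample titles place ASCL1 and the histone marks in basal medium, with EGF and FGF2 at 20 ng/ml each. FOXO3 was mapped after 4 hours in low growth factor signalling conditions followed by 1.5 hours with the PI3K inhibitor LY294002, which per the labels served to bring FOXO3 into the nucleus. Factor and medium therefore cannot be separated in any comparison of FOXO3 with the other lists.

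The submitters' processing notes list Bowtie 0.12.7, MACS2 and the mouse build mm9 for every sample. The deposited factor lists carry the name of the peak caller QuEST in their file names, and their track lines call them filtered. Each factor list pairs a region with 1 peak position: all 18291 ASCL1 and all 4329 FOXO3 regions held exactly 1 position, which lay inside the region and carried the region's score. Region numbers run to 19048 for ASCL1 and 5091 for FOXO3, with 757 and 762 numbers missing. The deposited histone lists hold MACS2 broad peaks, per the labels and the peak names in the file, and are called filtered in their track lines. Per the file headers the H3K27me3 list was also pooled. The filters, thresholds, control libraries and the pooling of replicates in the other lists are not given in the sources used here.

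The only measurement in these files is the score that the authors deposited for each interval. Its scale is not stated, so it was used to rank intervals within a list and never compared between lists. The exception to ranking was the copy number test of chromosome X, which assumed that scores scale with DNA copies. ASCL1 scores ran from 49.96 to 2407 and FOXO3 scores from 50.00 to 1259. Read counts and sequencing depth are unknown, and a deeper library yields more intervals, so the lengths of the lists are not measures of binding.

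There was 1 list per ChIP, so no test between samples was possible and no p-value is given. Shares of peaks carry a Wilson 95% interval, and differences between 2 shares a Newcombe 95% interval. These cover counting error over peaks only. Peaks are not replicates, and these intervals say nothing about how a second culture would behave. A peak was counted as overlapping when it shared at least 1 bp with an interval of the other list. Placement by chance was described with 1000 circular shifts of a list along each chromosome (the ASCL1 list for FOXO3 against ASCL1, otherwise the list whose share is given), which keep widths and clustering, and with 300 shifts or placements for each alternative. The span of a chromosome was taken from the lowest start to the highest end of all lists, 2576 Mb in total. A stricter comparison placed intervals of FOXO3 width 1000 times with their centres drawn at random inside H3K4me3 intervals, or inside H3K4me1 bases outside H3K4me3, in the numbers in which FOXO3 peaks fell into these classes.

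The code was tested on simulated lists of 4329 intervals. It recovered a share of 30.7% where 30% of intervals had been placed on ASCL1-width intervals, and a difference of 38.0 percentage points in a mark where 40 had been simulated. Without planted overlap the fold over shifted lists was 0.846 where 1 was simulated, and for intervals drawn at random in H3K4me1 the fold over placement in marked chromatin was 0.923, again against 1.

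The loci named were fixed by a rule before the data were examined: the 10 peaks of each factor with the highest score, the 10 shared sites with the smallest sum of FOXO3 and ASCL1 ranks, and the 5 widest intervals of each mark. The alternatives, also listed before the data were examined unless stated otherwise, were other definitions of overlap, 200 bp intervals, the upper 50% or 25% of lists by score, uniform placement, autosomes only, placement without regard to chromatin class, and matching on score rank. Coordinates are mm9 and count from 1. A genome sequence and gene annotation of mm9 were not used here, and the gene table at hand was made for a later build, so the planned assignment of peaks to genes, the gene lists and the motif counts were not run and loci are named by position alone. Computation used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.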

Results

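The binding sites of FOXO3 and ASCL1 and the distribution of H3K4me1, H3K4me3 and H3K27me3 were mapped in adult mouse neural progenitor cells, with 1 peak list for each. FOXO3 is a forkhead transcription factor that growth factor signalling keeps out of the nucleus. ASCL1 is a proneural basic helix-loop-helix factor. H3K4me1 marks enhancers and the flanks of promoters, H3K4me3 marks promoters, and H3K27me3 marks chromatin silenced by Polycomb. The FOXO3 list held 4329 peaks with a median width of 504 bp and the ASCL1 list 18291 peaks with a median width of 536 bp. H3K4me1 was listed at 84700 intervals covering 181 Mb, or 7.03% of the spanned genome. H3K4me3 covered 38.6 Mb in 21263 intervals, and H3K27me3 covered 44.9 Mb in 14218 intervals. The lists hold no read counts, so the depth behind them is unknown.

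The first comparison asked whether FOXO3 and ASCL1 occupy common sites, the question named in the series title. Of the 4329 FOXO3 peaks, 2001 overlapped an ASCL1 peak, a share of 46.2% (Wilson 95% interval 44.7 to 47.7). Because the ASCL1 list was longer, the same sites made up 10.97% of ASCL1 peaks (2006 of 18291, interval 10.5 to 11.4). Shifted ASCL1 lists overlapped 0.863% of FOXO3 peaks on average, and the highest of 1000 shifts reached 1.50%. The observed overlap was 53.6 times the shifted mean. With the upper 25% of both lists by score, the FOXO3 share was 23.1% and the ASCL1 share 5.49%. The ratio to the shifted mean ranged over the alternatives from 32.9 with peak positions within 1 kb to 126 with positions within 200 bp.

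Common sites were concentrated in high-scoring ASCL1 peaks, whereas the FOXO3 share varied less with score. The median rank percentile, where a higher value is a higher score, was 68.9 for shared and 48.0 for other ASCL1 peaks. For FOXO3 it was 52.0 and 48.7. In the highest-scoring 10% of FOXO3 peaks 47.9% (interval 43.2 to 52.6) overlapped ASCL1, against 43.6% (39.1 to 48.4) in the lowest-scoring 10%. For ASCL1 the share that overlapped FOXO3 was 25.2% (23.2 to 27.2) in the highest 10% and 6.45% (5.41 to 7.67) in the lowest. Shared peaks were also wider than the others. Their median width was 571 bp against 441 bp in the FOXO3 list, and 679 bp against 520 bp in the ASCL1 list. A wider peak meets the rule of 1 bp more easily, so part of this difference can follow from the definition. Width also went with score: the highest and lowest 10% had medians of 767 and 431 bp for ASCL1, and 600 and 462 bp for FOXO3.

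**Figure D1:**
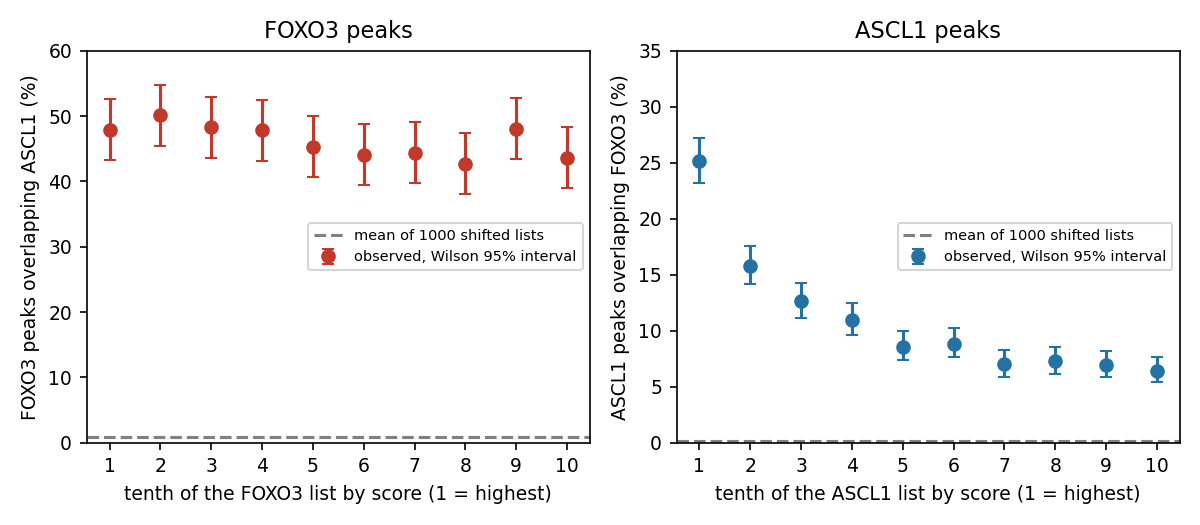
Share of FOXO3 peaks that overlap an ASCL1 peak (left) and of ASCL1 peaks that overlap a FOXO3 peak (right), in percent, in steps of 10% of each list ranked by the authors' score. Points are observed shares, bars Wilson 95% intervals and dashed lines the mean of 1000 shifted lists. The ASCL1 panel falls from 25.2% to 6.45%, while the FOXO3 panel stays between 42.7% and 50.1%.

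The peak positions of the 2 factors lay close together at common sites. Over the 2017 overlapping pairs the median distance between the FOXO3 and the ASCL1 position was 76 bp (interquartile range 32 to 164 bp), and 58.9% of pairs lay within 100 bp. When the relative positions within FOXO3 intervals were shuffled among FOXO3 peaks, the median distance averaged 106 bp, with a range of 98.7 to 115 bp over 1000 shuffles. Across all FOXO3 peaks, 17.2% had an ASCL1 position closer than 50 bp, where shifted lists gave 0.0733%. The 2328 FOXO3 peaks without an overlapping ASCL1 peak lay a median of 25255 bp from the next ASCL1 position.

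**Figure D2:**
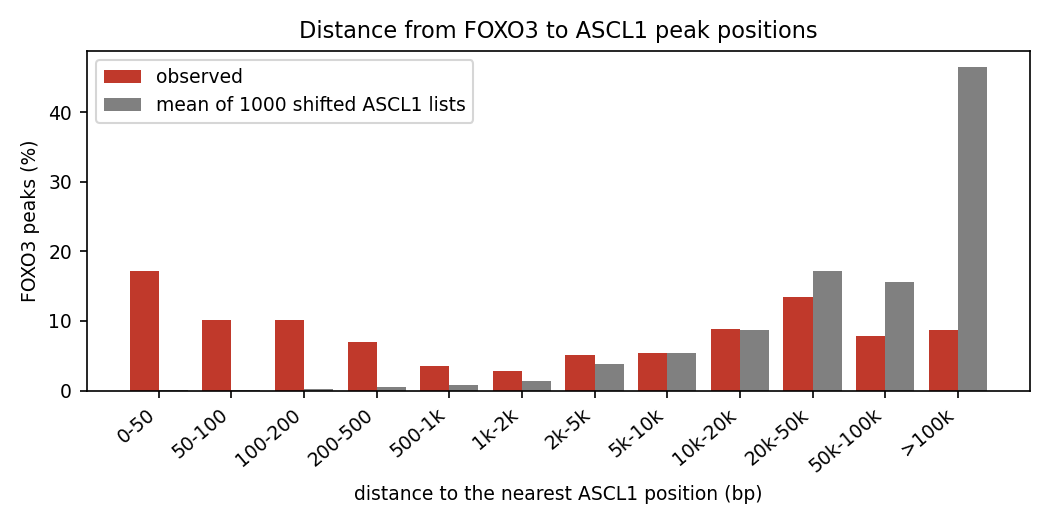
Percentage of FOXO3 peaks (vertical axis) by distance in bp from the FOXO3 peak position to the nearest ASCL1 position (horizontal axis, bins of unequal width), observed and as the mean of 1000 shifted ASCL1 lists. Observed peaks exceed the shifted lists most in the shortest bin, at 17.2% against 0.0733%.

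Both factors lay mainly in H3K4me1 chromatin, and FOXO3 peaks met H3K4me3 more often than ASCL1 peaks did. H3K4me1 was found at 81.5% of FOXO3 peaks (interval 80.3 to 82.6) and at 86.9% of ASCL1 peaks (86.4 to 87.4), where shifted lists gave 9.38% and 9.62%. H3K4me3 was found at 34.1% of FOXO3 peaks (32.7 to 35.5) and 25.8% of ASCL1 peaks (25.1 to 26.4), against 2.05% and 2.11% in shifted lists. The FOXO3 share in H3K4me3 was 8.32 percentage points higher than that of ASCL1 (Newcombe interval 6.79 to 9.88), and 7.81 points higher (5.88 to 9.73) when the ASCL1 list was reduced to its 4329 highest-scoring peaks. In H3K4me1 the difference of FOXO3 minus ASCL1 was -5.42 points (-6.70 to -4.19), and -13.8 points (-15.1 to -12.5) against the reduced list, of which 95.3% met H3K4me1. H3K27me3 was met by 3.58% of FOXO3 peaks and 4.81% of ASCL1 peaks, 1.71 and 2.26 times the shifted means. With only the upper 50% of H3K4me3 intervals by score, the H3K4me3 shares were 19.5% for FOXO3 and 14.0% for ASCL1. With the peak position in place of the whole peak, 3.12% of ASCL1 peaks lay in H3K27me3. All histone marks came from basal medium, whereas FOXO3 was mapped under LY294002.

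Sorted by combination of marks, 56.7% of FOXO3 and 64.6% of ASCL1 peaks carried H3K4me1 alone. A further 33.1% of FOXO3 and 24.6% of ASCL1 peaks met H3K4me3 without H3K27me3. Sites with both H3K4me3 and H3K27me3, a combination known from silent developmental promoters, made up 1.02% of FOXO3 and 1.15% of ASCL1 peaks. None of the 3 marks was listed at 6.65% of FOXO3 and 6.02% of ASCL1 peaks. The strongest FOXO3 peaks were the richest in H3K4me3, at 47.5% in the highest 10% and 30.7% in the lowest. For ASCL1 the corresponding H3K4me3 shares were 26.0% and 24.9%, whereas its H3K4me1 share was 97.9% in the highest 10% and 79.2% in the lowest.

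Common sites lay in H3K4me1 chromatin more often than the remaining peaks of either list. Among FOXO3 peaks, 93.0% of shared and 71.6% of unshared peaks met H3K4me1, a difference of 21.4 percentage points (Newcombe interval 19.2 to 23.5). FOXO3 peaks without ASCL1 were instead the ones richer in H3K4me3, at 37.7% against 29.9% of shared peaks, a difference of shared minus unshared of -7.79 points (-10.6 to -4.97). For H3K27me3 the FOXO3 difference was 1.15 points (0.0350 to 2.30). It was 0.194 points (-1.45 to 2.12) in the upper 50% of the lists and 1.85 points (0.682 to 3.12) with sharing defined by positions within 200 bp. Among ASCL1 peaks the shared ones were higher by 7.45 points (6.18 to 8.58) in H3K4me1 and by 5.12 points (3.04 to 7.27) in H3K4me3. Matching on score rank gave 4.38 points in place of 7.45 for H3K4me1, and the upper 50% of the lists gave 3.58. The H3K4me3 difference of ASCL1 was 3.40 points (0.00731 to 7.01) in the upper 50% of the lists and 1.42 points (-0.787 to 3.73) with positions within 200 bp. H3K27me3 differed by 0.0895 points between shared and unshared ASCL1 peaks, with an interval of -0.835 to 1.17, and by -0.798 points in the upper 50% of the lists. A shared FOXO3 peak lies at an ASCL1 peak by definition, and 86.9% of all ASCL1 peaks met H3K4me1. Shared peaks were also wider in both lists, which eases the rule of 1 bp for marks, and width was not matched.

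**Figure D3:**
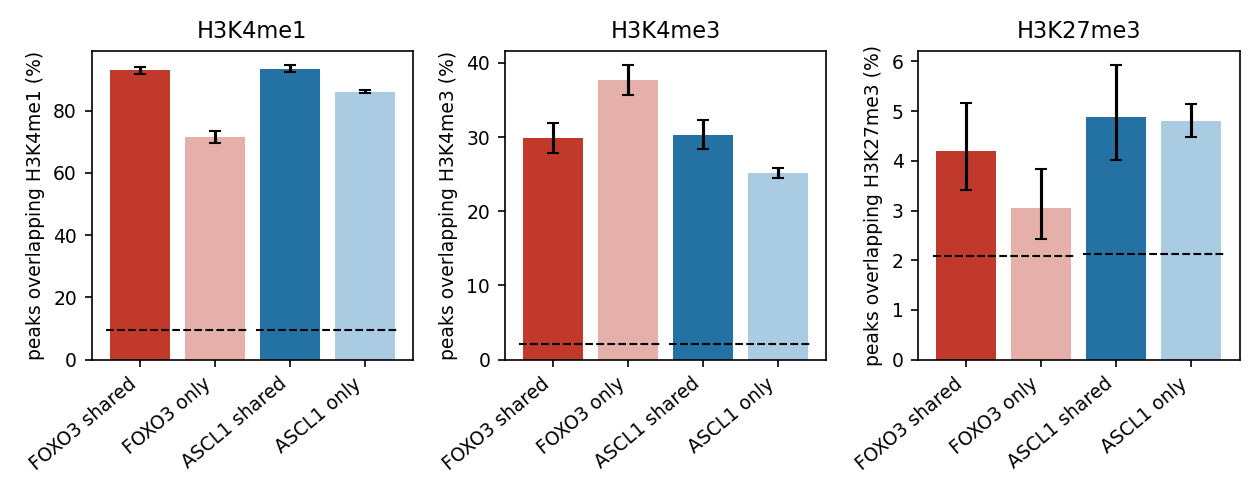
Percentage of peaks that overlap H3K4me1, H3K4me3 or H3K27me3 (vertical axes, scaled separately) for FOXO3 and ASCL1 peaks that are shared by both lists or found in 1 list only. Error bars are Wilson 95% intervals and dashed lines the shifted means for all peaks of the factor. H3K4me1 is lowest in the FOXO3-only peaks, at 71.6%.

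The share of FOXO3 peaks with ASCL1 differed widely between chromatin classes. It was 53.2% (interval 51.2 to 55.1) for peaks in H3K4me1 alone, 40.6% (38.1 to 43.2) in H3K4me3 without H3K27me3 and 66.3% (56.3 to 75.02) for the 95 peaks in H3K4me1 and H3K27me3 without H3K4me3. Among the 288 FOXO3 peaks with none of the 3 marks it was 10.8% (7.69 to 14.9). The overlap was next compared with placement in chromatin of the same class. Of the 4025 FOXO3 peaks in H3K4me1 or H3K4me3, 48.8% overlapped ASCL1, against 9.92% of placed intervals, a ratio of 4.92. The ratio was 6.05 in H3K4me1 without H3K4me3 and 3.45 in H3K4me3. It was 11.1 with 200 bp intervals. In the 1581 stretches of H3K4me1 or H3K4me3 that held exactly 1 position of each factor, with a median width of 3537 bp, the 2 peaks overlapped in 86.5% (84.8 to 88.1), whereas FOXO3 intervals placed at random within the same stretches overlapped ASCL1 in 39.1%.

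Among individual loci, the 4 highest-scoring FOXO3 peaks all met H3K4me3 and none overlapped ASCL1. They lay at 25758957 to 25759567 on chromosome 6 (score 1259), 52103427 to 52104918 on chromosome 7, 3230522 to 3231132 on chromosome 11 and 81025236 to 81025828 on chromosome 13. Of the 10 highest FOXO3 peaks 7 met H3K4me3, 8 met H3K4me1 and 6 overlapped ASCL1. The highest ASCL1 peak, at 84741857 to 84742591 on chromosome 3 (score 2407), lay in H3K4me1 without H3K4me3 and overlapped FOXO3. All 10 highest ASCL1 peaks met H3K4me1, 5 met H3K4me3 and 4 overlapped FOXO3.

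The shared site with the smallest sum of FOXO3 and ASCL1 ranks lay on chromosome 16, where FOXO3 covered 22517637 to 22518550 (rank 7) and ASCL1 22517564 to 22518509 (rank 41), with peak positions 138 bp apart. The next was on chromosome X, at 100728620 to 100729270 for FOXO3 (rank 30) and 100728504 to 100729188 for ASCL1 (rank 74), with positions 21 bp apart. After it came chromosome 7, with FOXO3 at 96983964 to 96984661 and ASCL1 at 96983830 to 96984771. All of the 10 shared sites with the smallest sums met H3K4me1, 2 of them met H3K4me3 and 0 met H3K27me3. Those with H3K4me3 were at 105882009 to 105883329 on chromosome 14 and 113243028 to 113243657 on chromosome 8.

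**Figure D4:**
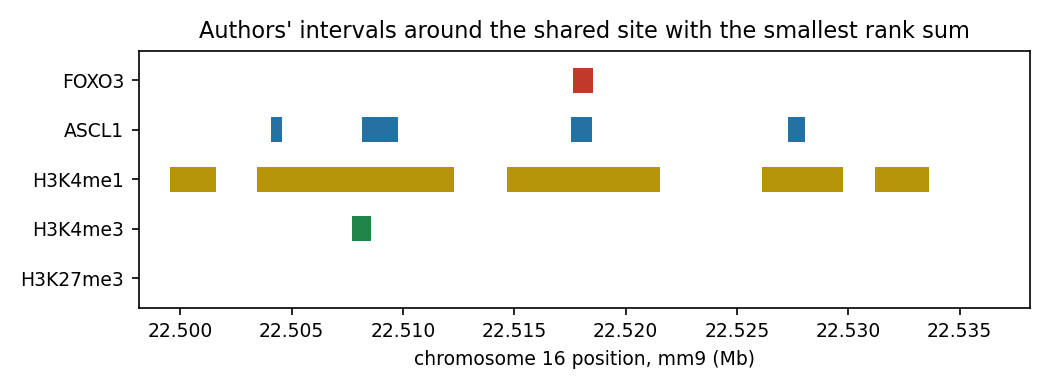
Intervals of the 5 lists (rows) along chromosome 16 in mm9 coordinates (Mb), 20 kb to each side of the FOXO3 position in the shared site with the smallest rank sum. The FOXO3 interval and the ASCL1 interval coincide inside an H3K4me1 interval from 22514683 to 22521548, and no H3K27me3 interval is listed in the window.

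The histone lists showed which marked intervals carried the factors. Among H3K4me1 intervals the widest were the most often occupied. In their widest quartile, with a median of 3809 bp, 36.2% held an ASCL1 peak and 10.1% a FOXO3 peak, against 4.09% and 0.661% in the narrowest. Per Mb of H3K4me1, ASCL1 positions were 93.0 in the widest and 50.4 in the narrowest quartile, and FOXO3 positions 22.2 and 5.78. Per Mb of H3K4me3 the order was the opposite, with 89.7 ASCL1 positions in the widest and 189 in the narrowest quartile, and 28.5 and 61.0 FOXO3 positions, while the widest H3K4me3 intervals also held a peak more often than the narrowest (ASCL1 28.9% against 14.2%, FOXO3 10.2% against 4.64%). H3K4me3 intervals free of H3K27me3 held ASCL1 in 21.8% (21.2 to 22.4) and FOXO3 in 7.34% (6.97 to 7.72). Those that met H3K27me3 held ASCL1 in 10.7% (9.63 to 11.9) and FOXO3 in 2.56% (2.04 to 3.21). H3K27me3 intervals that met neither H3K4 mark held 1.51 ASCL1 and 0.593 FOXO3 positions per Mb. Choosing intervals without an H3K4 mark leaves out most peaks of both factors. The density in chromatin without any of the marks was not computed, so these values do not show an effect of H3K27me3 itself.

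H3K4me3 and H3K27me3 coincided more often than shifted lists. Of H3K4me3 intervals, 13.4% (12.9 to 13.9) overlapped H3K27me3, against a shifted mean of 2.66%. The share was 4.76% with the upper 50% of each list by score. The 5 widest H3K27me3 intervals held 0 FOXO3 positions. ASCL1 had 0 positions in the widest, 102724883 to 102904426 on chromosome 15 (179544 bp), 1 in 52154327 to 52279661 on chromosome 6, 0 in 96111337 to 96219361 on chromosome 11, 6 in 119809964 to 119908002 on chromosome 4 and 5 in 100078241 to 100173013 on chromosome 6. The widest H3K4me3 interval, at 83852810 to 83881631 on chromosome 13, held 2 FOXO3 and 4 ASCL1 positions, and the next 4 held 0 or 1 FOXO3 and 1 or 2 ASCL1 positions each. The widest H3K4me1 interval, at 182270908 to 182342895 on chromosome 1, held 1 FOXO3 and 2 ASCL1 positions, and the next 4 held 0 to 3 FOXO3 and 2 to 10 ASCL1 positions each.

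Interval density on chromosome X lay outside the autosome range in all 5 lists. ASCL1 had 1.60 peaks per Mb on X against an autosome median of 7.43, with 5.53 as the lowest of the 19 autosomes. FOXO3 had 0.319 peaks per Mb on X against 1.76, and H3K4me1 6.85 intervals against 34.4. H3K4me3 had 4.20 per Mb on X against 8.71. H3K27me3 had 9.97 intervals per Mb on X against an autosome median of 4.94 and a maximum of 8.70, but these were narrower, with a median of 990 bp against 1834 bp. They covered 1.86% of X, within the autosome range of 1.02% to 3.07%.

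**Figure D5:**
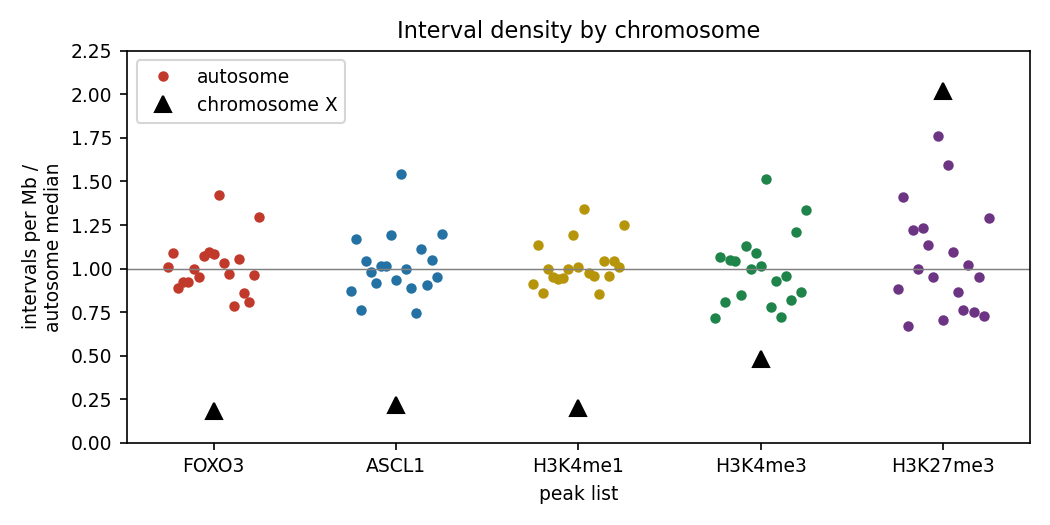
Intervals per Mb on each chromosome divided by the autosome median (vertical axis) for the 5 lists (horizontal axis). Circles are the 19 autosomes and triangles chromosome X, which lies below every autosome in 4 lists and above them in H3K27me3.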

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

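Among the tests in this part, that of mappability on chromosome X and the overlap without the top 5% of each list and H3K4me3 were chosen after the files were seen, and the former after its result was known.

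H3K4me3 was listed at 5 intervals on chromosome Y, and the other lists held 0.

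The overlap of FOXO3 with ASCL1 was 4.92 times that of intervals placed in H3K4-marked chromatin of the same class. That placement did not keep the preference of both factors for wide H3K4me1 intervals. In stretches with exactly 1 position of each factor, 86.5% overlapped, against 39.1% with placement inside the same stretch. Both comparisons argue against marked chromatin alone. Shifted lists kept the interval widths and overlapped 0.863% of FOXO3 peaks against 46.2% observed, which argues against wide intervals touching by chance. With 200 bp intervals the ratio to shifted lists was 124, but narrower intervals also meet less often in shifted lists, so this adds little. Nor was the overlap confined to the top 5% of each list by score or to H3K4me3. Without these peaks the FOXO3 share was 0.901 of the share over all peaks. The background samples were not analysed, so lower-scoring regions outside H3K4me3 that many ChIPs recover stay open. Separate neighbouring sites within a common open region stay open, because the distance between paired positions was 0.719 of that with shuffled positions, between the bounds of 0.6 and 0.9 set for either reading. Accessible sites narrower than the histone intervals were not measured and stay open as well. ASCL1 under LY294002 was not analysed here. Apart from separate neighbouring sites, no biological explanation was tested.

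Chromosome X carried few factor peaks and H3K4me1 intervals and many narrow H3K27me3 intervals. A smaller mappable part of X was considered as a common cause. H3K27me3 was not depleted there, with 2.02 times the autosome median density and 1.86% of X covered against an autosome median of 1.59%. The density cannot exclude mappability, because unmapped gaps could split wide intervals into more and narrower ones. Its bound was also set after the result was known. Filters that differed between the lists stay open as well. A single X copy could lower the scores and leave fewer peaks above the cut-off: the density of all ASCL1 peaks on X was 0.495 (exact Poisson interval 0.437 to 0.559) of the autosome median density of peaks with at least 2 times the lowest score, between the bounds of 0.4 and 0.6, and the FOXO3 ratio was 0.852 (0.636 to 1.12), so copy number stays open. Both ratios assume that scores scale with DNA copies, which is not known. The listed H3K27me3 intervals were not spread more evenly over X than over the autosomes. After thinning X to the autosome median density, 72.2% of its 1 Mb windows held an interval, within the 61.8% to 89.9% of the autosomes as listed. With all chromosomes thinned to the lowest density the share was 65.8% against 59.0% to 75.9%. Unmapped stretches or filters could also empty windows, so these shares cannot decide on H3K27me3 spread evenly along an inactive X. Banded spread was not tested. Of the H3K27me3 intervals on X, 85.5% met neither H3K4 mark, against 54.1% on autosomes. H3K4me1 covered only 1.16% of X against an autosome median of 7.20%, and narrower intervals meet other marks less easily, so part of this contrast can follow from these. The labels give no sex. The 5 H3K4me3 intervals listed on chromosome Y would require cells with a Y chromosome if their reads were placed correctly. The share of such cells was not measured, so sex is not settled.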

How the results depend on the processing

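The exclusion of the top 5% of each list and of H3K4me3 was chosen after seeing the data. Of 64 alternatives, 22 kept their value within the 95% interval of the main value, 42 moved outside it and 0 turned the direction of a result whose main interval excludes no difference. Many of the alternatives are shares, which have no direction to turn, so the count of 0 bears only on folds and differences. The sign alone turned in 2 of the 22, both for H3K27me3 in shared minus ASCL1-only peaks, with -0.798 points in the upper 50% and -0.167 matched on rank, where the main interval of -0.835 to 1.17 includes 0. An upper 50% or 25% of a list holds fewer peaks by construction, and the cause of other shifts was not tested. The share of FOXO3 peaks with ASCL1 was 37.6% with positions within 200 bp, 48.1% within 1 kb, 32.2% and 23.1% in the upper 50% and 25%, and 41.7% without the top 5% and H3K4me3. The ASCL1 share was 8.90% within 200 bp, 11.7% within 1 kb, and 7.64% and 5.49% in the upper 50% and 25%. The fold over shifted lists was 87.0 at an overlap of 50% of the smaller interval, 126 within 200 bp, 32.9 within 1 kb, 67.5 and 86.9 in the upper 50% and 25%, 71.4 without the top 5% and H3K4me3, and 124 with 200 bp intervals. Over placement in marked chromatin it was 5.15 without regard to class, 6.06 in the upper 50% and 11.1 with 200 bp intervals. With the peak position inside the histone interval, FOXO3 shares were 77.4% in H3K4me1, 30.2% in H3K4me3 and 2.49% in H3K27me3, and ASCL1 shares 83.4%, 22.7% and 3.12%. With the upper 50% of factor peaks, FOXO3 met H3K4me3 in 36.6%, and ASCL1 met H3K4me1 in 91.8% and H3K27me3 in 5.17%. With the upper 50% of histone intervals, FOXO3 shares were 71.4% in H3K4me1 and 19.5% in H3K4me3, and ASCL1 shares 73.1%, 14.0% and 3.95% in H3K4me1, H3K4me3 and H3K27me3. The share of H3K4me3 intervals in H3K27me3 was 10.5% at an overlap of 50% of the smaller interval, 4.76% in the upper 50% and 11.2% from 1 kb. Shared minus FOXO3-only peaks differed by 19.1 points in H3K4me1 within 200 bp, and in H3K4me3 by -11.3 points in the upper 50% and -11.5 within 200 bp. Shared minus ASCL1-only peaks differed in H3K4me1 by 3.58 points in the upper 50% and 4.38 matched on rank, and in H3K4me3 by 1.42 within 200 bp. The unknown depth limits each list: peaks under an author's cut-off are missing, so a peak called unshared can lie just below it in the other list. No paired analysis was possible because there was 1 list per ChIP. Gene assignment, gene lists and motifs, planned before the data were examined, were not run because no mm9 annotation or genome was used here.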

Other observations

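The association described first was noticed in the data, and the matched test of it was set before its own result was seen.

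H3K4me1 intervals outside H3K4me3 that touched an H3K27me3 interval held both factors more often than those that did not. Of these 3163 intervals, 35.6% held an ASCL1 peak and 8.79% a FOXO3 peak, against 14.5% and 3.14% of the 61752 intervals that did not touch H3K27me3. The differences were 21.1 percentage points (Newcombe interval 19.5 to 22.8) for ASCL1 and 5.65 points (4.70 to 6.69) for FOXO3. Within the touching intervals the factors lay mostly on the side free of H3K27me3: 27.1% of the 1267 ASCL1 positions (24.7 to 29.6) and 21.7% of the 286 FOXO3 positions (17.3 to 26.8) were inside H3K27me3, where 50.2% of the bases lay.

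Width and score of the H3K4me1 intervals were tested as a technical explanation. Matched in 10 by 10 bins of width and score, the ASCL1 difference was 14.5 points, above the bound of 10 set for excluding them as the whole cause. For FOXO3 the matched difference was 3.75 points, against 5.65 unmatched. The bound was set for ASCL1 only and lies above the unmatched FOXO3 difference, so no verdict is given for FOXO3. Accessibility of these intervals and the genes near them were not tested.

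FOXO3 peaks without an overlapping ASCL1 peak still lay near ASCL1 more often than in shifted lists. Of these 2328 peaks, 27.9% had an ASCL1 position within 10 kb, against 12.0% in 200 shifted lists. Shifting ignores the marks, and 71.6% of these FOXO3 peaks met H3K4me1. Placement in marked chromatin was not run for this distance, so clustering of marked chromatin alone stays open.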
